A study of Mus musculus with 288 samples.

How the data were processed

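The samples were single cells sorted from the lungs of C57BL/6 mice of 4 months that carried Scgb1a1-CreER, a drug-inducible recombinase under the promoter of the club cell secretoglobin gene, and Rosa26-mTmG, a reporter that switches its fluorescent protein after recombination. Per the labels, the gate took epithelial cells (Epcam positive) without the leukocyte marker CD45 or the endothelial marker CD31, low in CD24 and positive for the Scgb1a1 lineage. There were 286 wells with a sorted cell and 2 negative control wells. No label names the animal a cell came from, so the 286 cells were treated as 1 sample, and no p-value or standard error was made from cells. Counts of list members that were higher or lower describe the pooled classes of this 1 sample and are not tests.

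Per the labels' protocols, a fixed number of ERCC spike-in molecules was added to each tube, RNA was fragmented by heat, cDNA was primed from the poly(A) tail with a primer holding a molecular barcode, a common end was added by template switching, and the cDNA was amplified with indexed primers. The submitters' processing notes name the aligner STAR, without a version, and the genome build mm10. The gene annotation, the counting tool, and whether a molecular barcode was collapsed to 1 count are not given in the sources used here. The deposited table holds whole-number counts per gene symbol and well, made by the authors and not normalized, for 24781 genes and 288 wells. Every interval given here covers counting error only and treats counts as independent. If barcodes were not collapsed, copies made by PCR were counted separately, and the intervals and the calls that rest on them are then too narrow and too many. The table used here holds no spike-in and no mitochondrial gene. The planned spike-in ratio was therefore not computed, and the planned filter on mitochondrial counts removed nothing. Of the symbols, 24241 matched the GENCODE M21 annotation and 24127 the RefSeq annotation, and coordinates are given from GENCODE M21 on the same assembly as mm10 (GRCm38). Goblet marker Muc16 was not analysed here. No 2 wells held identical counts. Counts were not stated to use strand, and genes with near-identical copies are uncertain, among them Rpl26 and Gm15772, whose counts were equal in 287 of the 288 wells, and the class I genes H2-K1 and H2-D1.

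A well was kept when its total was above 10 times that of the higher control, it detected at least 500 genes and at most 20% of its counts were mitochondrial. The higher control held 234 counts, which put the limit at 2340 counts. This limit removed 59 of the 286 wells, the filter on genes removed no further well, and 227 cells were kept. No doublet caller was run on so few cells, and second cells in a well were weighed in the closing section from totals and marker counts.

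Population levels were pooled CPM (the summed count of a gene over the summed total of the cells, scaled as usual) with exact Poisson intervals, and shares of cells had exact Clopper-Pearson intervals, all at 95%. A count of 0 was read as allowing up to 3 counts or cells. For shares at equal depth, each cell was thinned without replacement to 3151 counts, the 10th percentile of the kept totals, which left out 23 shallower cells. Cells were clustered with scanpy 1.11.5 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2, Python 3.11.15). Counts were scaled to 10000 per cell and log-transformed after adding 1. The 2000 most variable genes, without any gene of the gene group lists, gave 20 principal components, a graph of 15 neighbours and Leiden clusters at resolution 0.5 with seed 0. The cluster of highest Sftpc CPM was named AT2-like, and of the others the cluster of highest Scgb3a1 CPM was named Scgb3a1-high. The remaining cluster was named club-like. Both genes belong to marker lists fixed before the data were examined. The Scgb3a1-high cluster, with leading genes of 3 lists, was named after a gene, not a cell type. The club-like class held 1 club and 1 ciliated marker among its 10 leading genes, so its name is less certain than that of the AT2-like class. A second clustering at resolution 1.0 was used to describe smaller clusters.

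Classes were compared by the ratio of pooled CPM per gene, with an exact conditional binomial interval. A gene was called higher or lower by a rule of size and counting error, not by a test across animals, when the ratio was at least 2-fold, its interval excluded 1 and both classes together held at least 20 counts (a measured gene). Against a class at 0 counts the ratio was computed with 3 counts in its place. A list was described by how many measured members were higher or lower and by the percentile of its median log2 ratio among 10000 random lists of the same size matched on mean expression, for lists of at least 3 measured members. Genes used in the clustering were not taken as results. No test across animals was possible, and there is no replicate check of any difference.

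The named genes followed a rule fixed before the data were examined. It took all genes of the sort gate; the 10 genes of highest pooled CPM other than mitochondrial and ribosomal protein genes; between the 2 largest named classes, the 10 highest and 10 lowest ratios among genes outside the clustering with at least 100 counts; up to 4 members of each gene group list with the largest absolute log2 ratio and at least 100 counts, or the 2 of highest CPM; the 3 members of highest CPM of each cell type list; and for any other class the 5 highest ratios to the largest class among genes outside the clustering with at least 50 counts. The gene group lists were MHC class II, MHC class I, interferon response, xenobiotic metabolism, lipid synthesis, lysosome, unfolded protein response, immediate early genes, cell cycle, Notch, Wnt, BMP and TGF-beta, transitional epithelium, lung transcription factors, antimicrobial and inflammatory genes, progenitor surface markers, oxidative phosphorylation and sex-linked genes. The cell type lists were club, alveolar type 2 (AT2), alveolar type 1 (AT1), ciliated, basal, goblet, neuroendocrine, tuft, endothelial, immune, mesenchymal and erythroid. In this rule the 2 largest named classes were taken as club-like (98 cells) and AT2-like (63 cells). The Scgb3a1-high class, not named by cell type, was treated as the other class, although with 66 cells it was larger than the AT2-like class.

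The comparison was first tested on simulated counts with 200 genes changed by known folds. Counts were drawn from a mean profile shared by the compared classes and from the real class totals. The draws held counting error only, which is the model the interval assumes, and spread between cells was not simulated. The values below therefore describe the rule under that model, and cannot show its coverage or false calls in the real data. For AT2-like against club-like cells, over 3766 genes, 63.0% of genes changed 2.5-fold and 84.0% of those changed 4-fold were called, 2.10% of unchanged genes were called and 96.3% of intervals held the true ratio. For Scgb3a1-high against club-like cells, over 4530 genes, these values were 71.0%, 88.0%, 2.19% and 96.0%.

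The labels name no plate or run. The column order of the table was split into 3 sets of 96 columns as a possible technical batch, since 96 is a common plate size, and each class comparison was repeated within each set. Alternatives fixed before the data were examined changed the filters on genes and controls, the counts that make a cell positive, the depth, the clustering (resolution, variable genes, components, gene group lists kept in, scran 1.30.0 size factors in R 4.3.3), the weighting of cells, the scaling (TMM factors of edgeR 4.0.16), the count minimum and the fold. Alternatives chosen after seeing the data used totals without ribosomal RNA or without Scgb1a1 and Sftpc, counts above the control wells, no limit from the controls, and comparisons without 10 ciliated-like cells, without the last 96 columns or without the cell that held most counts of a gene in each class. The closing section gives their effect.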

Results

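The 286 sorted wells and the 2 negative control wells were compared first, since the controls show how many counts a well without a cell can hold. Summed over the kept wells, Scgb1a1, the club cell secretoglobin, was the most abundant gene. Sftpc, surfactant protein C of alveolar type 2 cells, was abundant in part of these wells. Sorted wells held a median of 4802 counts (range 13 to 15088) and 1413 detected genes (range 8 to 2898). The controls held 41 counts of 15 genes and 234 counts of 77 genes. Scgb1a1 gave 20 and 18 of these control counts, the ribosomal RNA gene Rn45s gave 8 in each, Scgb3a2 gave 1 in each, and Sftpc gave 0 in both. In the second control, Stxbp3-ps and Scn2b gave 65 and 41 counts, genes singled out after their values were seen.

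**Figure D1:**
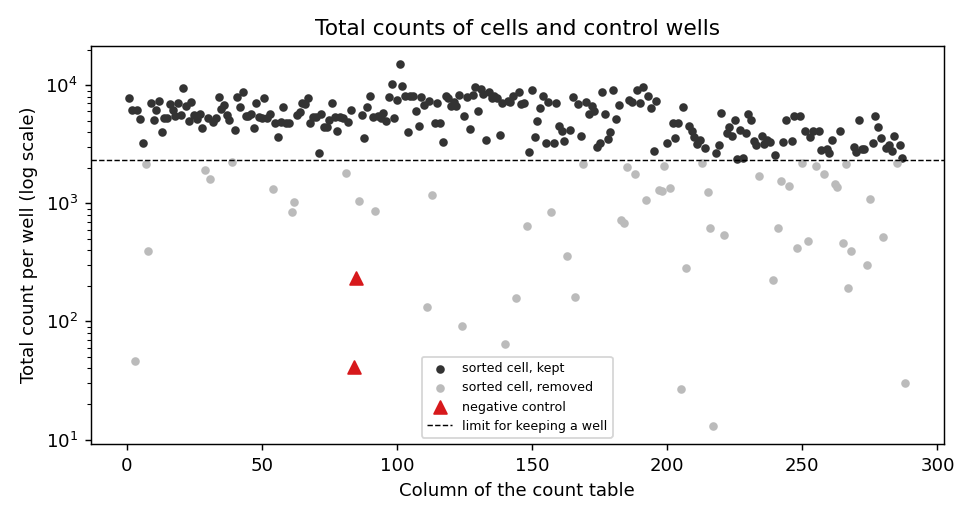
Total counts per well (log axis) by position in the deposited table, for 286 sorted cells and 2 negative control wells, with the limit of 2340 counts as a line. The 227 kept cells lie between 2384 and 15088 counts, and the controls hold 41 and 234.

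After the filter 227 cells were kept, with a median total of 5356 counts (range 2384 to 15088), a median of 1528 genes (range 762 to 2898) and 1259118 counts in all. The 59 removed wells held a median of 1035 counts, of which Rn45s took a median of 22.6%, against 8.90% in kept cells. Of the 24781 genes, 13111 had a count in some well. In the 3 successive sets of 96 columns, 82, 81 and 64 cells were kept, with median totals of 5473.5, 7063 and 3576.5 counts.

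The kept cells as a population were rich in secretoglobins, in surfactant protein and in the club cell enzymes Cbr2 and Cyp2f2. Scgb1a1 (chromosome 19, 9083636 to 9087958) had 223932 CPM (95% interval 223106 to 224760) and at least 1 count in each of the 227 cells, or 22.4% of all kept counts. Sftpc (chromosome 14, 70520949 to 70524081) had 29251 CPM (28953 to 29552), and 61.7% of cells held a count of it (55.0 to 68.0%). The other genes among the 10 most abundant were Rn45s at 95055 CPM, the secretoglobins Scgb3a2 and Scgb3a1 at 25778 and 20782, carbonyl reductase Cbr2 at 19120, the cytochrome P450 Cyp2f2 at 13966, the airway surface protein Bpifa1 at 11337, Wfdc2 at 7778 and surfactant protein Sftpa1 at 7771. Scgb3a1 was detected in 48.5% of cells and Bpifa1 in 33.0%.

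Transcripts of the sorted proteins were compared with the gate. Epcam had 92.1 CPM and a count in 37.9% of cells (31.6 to 44.5%), a share that was 23.5% in cells thinned to equal depth and 1.76% from 3 counts, and Cd24a, which encodes the protein on which the cells were sorted as low, had 490 CPM and a count in 81.5% (75.8 to 86.3%), or 75.0% thinned and 44.5% from 3 counts. Ptprc (CD45) and Pecam1 (CD31) had no count in 227 cells, which allows a share of up to 1.32% of cells with a count. None of Epcam, Cd24a, Ptprc and Pecam1 had a count in either control.

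Markers of endothelial, immune, mesenchymal, erythroid, neuroendocrine and tuft cells were rare. Some goblet and AT1 genes were common, with Muc5b in 38.8% and Aqp5 in 64.3% of cells. Of the endothelial list, Kdr had a count in 12 cells, Cdh5 in 4 and Cldn5 in 2. Cd68 and Mrc1 of the immune list were found in 6 cells and 1 cell. The mesenchymal genes Mgp, Col1a1 and Dcn were found in 2, 1 and 1 cells, and the hemoglobin genes Hba-a1 and Hba-a2 in 4 cells each with Hbb-bs at 0. Neuroendocrine Calca, Uchl1 and Syp were found in 4, 2 and 2 cells, and tuft cell genes Dclk1, Avil and Trpm5 in 6, 1 and 0 cells. Summed over each whole list, the club-like class described next had 8.78 CPM of neuroendocrine, 7.03 of tuft, 29.9 of endothelial, 7.03 of immune, 1.76 of mesenchymal and 10.5 of erythroid genes. Among basal genes, Krt15 had 92.1 CPM, Aqp3 22.2 CPM and Trp63 a count in 1 cell. The ciliated genes Tppp3, Foxj1 and Ccdc153 had 101, 38.1 and 31.8 CPM, with Foxj1 in 8 cells, and the goblet genes Tff2, Muc5b and Agr2 had 1052, 1005 and 102 CPM. The AT1 genes Ager, Aqp5 and Hopx had 247, 232 and 126 CPM.

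The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had a count in 39, 20, 12 and 1 cells, and Xist, the RNA of the inactive X chromosome, in 1 cell. The proliferation genes Mki67 and Top2a were detected in 3 and 2 cells.

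Club and alveolar type 2 markers were then compared within single cells, since the cells were sorted by the Scgb1a1 lineage. Scgb1a1 and Sftpc were both detected in 140 of 227 cells, or 61.7% (55.0 to 68.0%), and because Scgb1a1 was present in each cell, the product of the single shares was the same 61.7%. More than 20 counts of each, the highest Scgb1a1 count of a control, were held by 40 cells, or 17.6% (12.9 to 23.2%). The product of the single shares at that limit was 24.8%. Of these 40 cells, 38 belonged to the AT2-like class and 2 to the club-like class. Sftpc had 154974 CPM in AT2-like cells, 555 CPM in club-like cells (239 without the cell of most Sftpc counts) and 106 CPM in Scgb3a1-high cells. In Scgb3a1-high cells, 48.5% held an Sftpc count at a median total of 7040, and no cell held more than 4, while each of the AT2-like cells held one at a median total of 3449. At an equal depth of 3151 counts, 48.0% of 204 cells held both genes, with 44 AT2-like, 66 Scgb3a1-high and 94 club-like cells deep enough. Both genes reached 3 counts in 71 cells (31.3%, product of single shares 32.2%). Both were above the control wells in 116 cells (51.1%, product 54.3%). In AT2-like cells the median Scgb1a1 count was 34 (range 1 to 1681), with 39 of 63 cells above the controls, against medians of 1790 in club-like and 1535 in Scgb3a1-high cells. Both controls lie in the first set of 96 columns, and 5 nearly empty sorted wells of the middle set, with no more counts than the higher control, held 21 to 36 Scgb1a1 and up to 2 Sftpc counts. Against the nearly empty wells of their own set, both genes were above in 84 cells (37.0%), and Scgb1a1 was above in 42 of the 63 AT2-like cells.

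**Figure D2:**
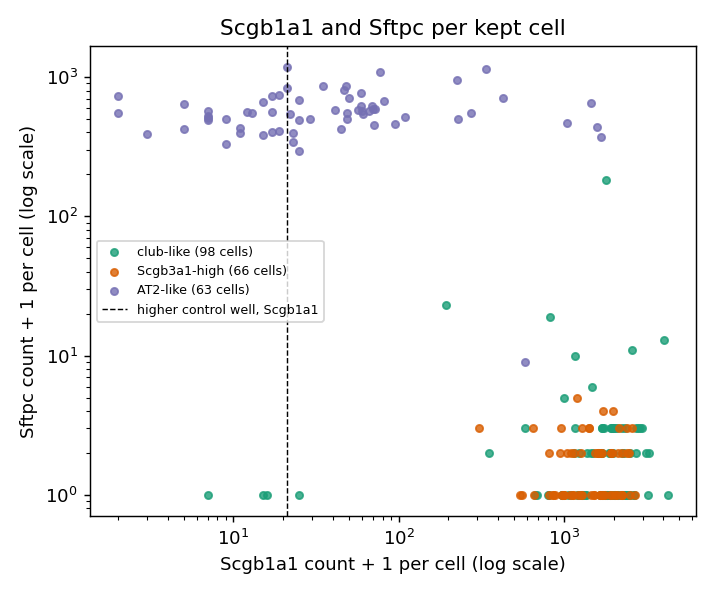
Counts plus 1 of Scgb1a1 (horizontal) and Sftpc (vertical), both on log axes, in each of the 227 kept cells, coloured by class, with the higher control count of Scgb1a1 as a dashed line. AT2-like cells lie at high Sftpc with a median of 554 counts, apart from 1 cell with 8, and most club-like and all Scgb3a1-high cells at high Scgb1a1 with medians of 1790 and 1535, club-like counts reaching down to 6.

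Clustering gave 3 classes. A club-like class held 98 cells (43.2%, interval 36.6 to 49.9%), a class named here Scgb3a1-high held 66 (29.1%, 23.3 to 35.4%) and an AT2-like class held 63 (27.8%, 22.0 to 34.1%). The 10 leading genes of the AT2-like class included 7 AT2 markers, among them Sftpc, Lyz2, Napsa and Slc34a2. The 10 leading genes of the club-like class held 1 club marker, the haptoglobin gene Hp, and 1 ciliated marker, Tppp3, whose counts lay mostly in 10 cells that formed a ciliated-like cluster at resolution 1.0. Those of the Scgb3a1-high class held 3 goblet markers (Tff2, Muc5b and Agr2), 1 club marker (Scgb3a1) and 1 AT1 marker (Pdpn), so it was not named by cell type. Median totals were 5487 counts in club-like, 7040 in Scgb3a1-high and 3449 in AT2-like cells.

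The classes were spread unevenly over the table. In the 3 successive sets of 96 columns, AT2-like cells made up 6.10% (2.01 to 13.7%), 21.0% (12.7 to 31.5%) and 64.1% (51.1 to 75.7%) of kept cells. Scgb3a1-high cells made up 41.5%, 35.8% and 4.69%, and club-like cells 52.4%, 43.2% and 31.2%. Among the wells removed for low totals, 6, 1 and 9 in the 3 sets held over 100 Sftpc counts, and counting these as AT2-like would give 12.5%, 22.0% and 68.5%. Shares over all sets therefore depend on how many wells of each set were kept, and without the last 96 columns the AT2-like share was 13.5% and the Scgb3a1-high share 38.7%.

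**Figure D3:**
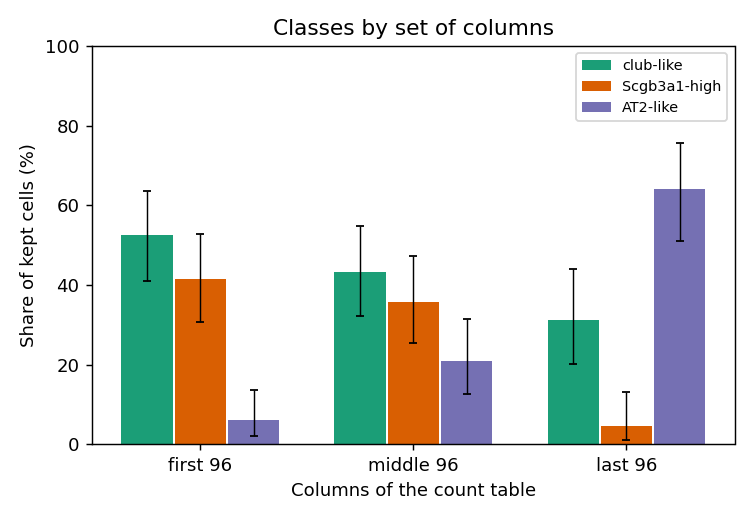
Share of kept cells (percent, from 0) in each class in the 3 successive sets of 96 columns, with bars for exact 95% Clopper-Pearson intervals. The AT2-like share is 6.10%, 21.0% and 64.1%.

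AT2-like cells were set against club-like cells to describe what distinguished alveolar from airway secretory cells of the same lineage label, using genes that had no part in the clustering. Lipid synthesis and MHC class II genes were higher in AT2-like cells, and xenobiotic metabolism genes were lower. The fatty acid binding protein Fabp5 was 167-fold higher (95% interval 45.4 to 1392), the stearoyl-CoA desaturase Scd1 40.2-fold (32.4 to 50.5), and fatty acid synthase Fasn 14.4-fold (9.78 to 21.7). The class II alpha chain H2-Aa was 54.2-fold higher (22.5 to 170) and the class II invariant chain Cd74 36.8-fold (24.5 to 57.6). The cytochrome P450 Cyp4b1 was lower at a log2 ratio of -3.50 (-4.35 to -2.76). Fabp5 lies on chromosome 3 (10012548 to 10016607), Scd1 on chromosome 19 (44394455 to 44407879) and Cd74 on chromosome 18 (60803848 to 60812652).

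Of 16 measured lipid synthesis genes, 13 were higher, 0 lower and 3 neither, with a median log2 ratio of 2.42, at percentile 100 of matched random lists. The elongase Elovl1 was 17.2-fold higher (12.5 to 24.2) and the desaturase Scd2 12.8-fold (8.54 to 19.7). The median was 2.75, 3.21 and 2.15 within the 3 sets of columns. The first set held only 5 AT2-like cells, 3 of them with at least 200 Scgb1a1 counts, which limits all its values. There 3 of 5 measured lipid synthesis genes were higher. All 4 measured MHC class II genes were higher, with a median of 5.48 (percentile 100), and medians of 5.04, 5.67 and 3.69 within the sets, over 1, 2 and 4 measured genes. Of 5 measured class I genes, H2-K1 and H2-D1 were higher at 2.25-fold (1.72 to 2.95) and 2.04-fold (1.57 to 2.66), the list median was 0.60 (percentile 88.4, and -0.05, 0.75 and 0.54 within the sets), H2-K1 and H2-D1 were at -0.05 and -0.74 in the first set, and neither gene kept a 2-fold difference with TMM factors (log2 ratios of 0.86 and 0.72). Of 17 xenobiotic metabolism genes, 16 were lower and 0 higher, with a median of -2.14 (percentile 0) and -1.07, -2.13 and -2.29 within the sets. In the first set, with its 5 AT2-like cells, 4 of 14 measured genes were lower and 0 higher. The glutathione transferases Gsto1 and Gstm2 were lower at -3.34 (-4.16 to -2.62) and -2.44 (-3.24 to -1.73).

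Of 14 lung transcription factors, 7 were higher and 1 lower, with a median of 0.91 (percentile 99.7) and 1.11, 0.63 and 1.19 within the sets. The ETS factor Etv5 was 45.2-fold higher (23.2 to 100), Cebpa 4.71-fold (3.12 to 7.20) and Nkx2-1, a factor of lung epithelial identity, 2.37-fold (1.58 to 3.56), while Cebpd was neither. Of 18 immediate early genes, 6 were higher and 1 lower (median 0.70, percentile 99.9, and 0.88, 0.57 and 0.45 within the sets), with Klf4 at 4.84-fold (3.18 to 7.48), Jund at 2.85-fold, Fos at 2.21-fold and Ier3 lower at -1.12. Of 13 lysosome genes, 3 were higher and 1 lower (median 0.13, percentile 53.8, and -0.18 with TMM factors). These 3 were the cathepsins Ctsc at 5.83-fold (4.46 to 7.70) and Ctsh at 3.02-fold and the sterol carrier Npc2 at 2.12-fold (1.93 to 2.33), and Psap was lower at -1.55 (-2.51 to -0.70).

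Of 10 antimicrobial and inflammatory genes, 7 were lower and 1 higher (median -1.27, percentile 0, and -0.92, -1.27 and -0.81 within the sets). The immunoglobulin transporter Pigr was lower at -3.45 (-4.92 to -2.30), Wfdc2 at -1.15 (-1.26 to -1.04) and complement C3 at -1.40, while Lcn2, which binds bacterial siderophores, was 7.76-fold higher (5.48 to 11.2). Reg3g was lower at -2.51 (-4.43 to -1.07) from 4 counts in AT2-like cells, and Bpifa1 at -1.07 (-2.15 to -0.12), a call lost in most alternative clusterings, with a sign change to 0.05 with scran size factors. Of 13 transitional epithelium genes, 6 were lower and 1 higher (median -0.83, percentile 0.020, and -1.13, -1.26 and -1.26 within the sets). The keratin Krt19 was at -2.21 (-2.88 to -1.61), Anxa1 at -2.08 and Clu at -1.05 (-0.74 with 10 principal components), and S100a6 at -1.99 was at -0.95, no longer 2-fold, without the 10 ciliated-like cells. Of 5 Notch genes 3 were lower and 0 higher (median -1.08, percentile 0.83), with Hes1 at -0.85. Of 3 Wnt genes 1 was higher and 1 lower, the latter the cyclin Ccnd1 at -1.33 (-1.70 to -0.98), with a median of 1.27 (percentile 96.3). Ccnd1 was the 1 Wnt gene measured within each set, at -1.41, -1.64 and -0.47. Of 6 BMP and TGF-beta genes 2 were higher and 1 lower (median 0.79, percentile 92.0), with Id2 at 5.16-fold (3.08 to 8.87). Of 3 progenitor surface genes 2 were lower, among them Ly6a at -3.28 (-6.37 to -1.35) from 2 counts in AT2-like cells, and the median of -1.73 (percentile 0.52) was 0.05 without the count minimum. Of 3 interferon response genes 1 was lower, Ifitm3 at -1.63 (median -0.09, percentile 26.1).

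No oxidative phosphorylation gene of 13 was higher or lower (median -0.22, percentile 5.28), Atp5b being at -0.23. Of 11 unfolded protein response genes 1 was higher and 0 lower (median -0.01, percentile 28.1), with Manf at -0.78 and Atf4 at 0.64. The 1 measured cell cycle gene, Pcna, was neither, at 0.39. The 1 measured sex-linked gene, Ddx3y, was 2.82-fold higher (1.21 to 6.68) from 14 and 12 counts, and log2 1.19, no longer called, with TMM factors. Of the genes outside the lists, the claudin Cldn10 was lower at -5.82 (-11.14 to -3.32) from 1 count in AT2-like cells, Emp1 at -3.51 (-5.41 to -2.11), the sulfhydryl oxidase Qsox1 at -3.15 (-4.49 to -2.07) and Slc16a11 at -2.99 (-4.01 to -2.12). The retinaldehyde dehydrogenase Aldh1a1, itself on the club list, was at -4.68 (-5.28 to -4.15), and Scgb3a1 of the same list at -4.54 (-5.22 to -3.93).

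Some list members outside the rule for named genes are named here because few of their list were called, and they were chosen after their values were seen. In AT2-like cells the class II chains H2-Ab1 and H2-Eb1 were 69.0-fold (18.2 to 583) and at least 25.0-fold higher, H2-Eb1 from 31 counts against 0. Sox2, a transcription factor of conducting airway epithelium, was the transcription factor that was lower, at a ratio of 0.054 (0.001 to 0.315) from 1 count. The lower Notch genes were the receptors Notch1 and Notch2 and the feedback regulator Nrarp, at log2 ratios of -1.17, -1.08 and, for Nrarp from 2 counts, -3.63 (-6.71 to -1.72). The higher Wnt gene was the feedback regulator Nkd1, at 33.9-fold (8.54 to 293) from 28 and 2 counts. In the BMP and TGF-beta list the pseudoreceptor Bambi was 8.30-fold higher (3.47 to 22.8) and the ligand Tgfb2 was lower at 0.097 (0.002 to 0.591) from 1 count. The growth factor Areg was the transitional epithelium gene that was higher, at 6.11-fold (3.53 to 11.0), the chaperone Dnajb9 the unfolded protein response gene that was higher, at 2.64-fold (1.42 to 4.94), and Itgb4 the other progenitor surface gene that was lower, with 0 counts against 24, so that the median of that list is a bound.

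Markers of other cell types also differed between these classes. Of 5 measured AT1 genes 3 were higher and 1 lower in AT2-like cells (median 1.04, percentile 97.8), with Ager, Aqp5 and Emp2 higher, Hopx lower, and Ager at 956 CPM against 148. Of 4 ciliated genes 3 were lower (Foxj1, Tppp3 and Ccdc153; median -1.82), but the 10 ciliated-like cells held 46 of 46, 95 of 100 and 35 of 35 of their club-like counts, so this is not a difference from most club-like cells, and of 3 goblet genes Muc5b and Tff2 were lower and Creb3l1 higher (median -4.61). Of 12 club genes 11 were lower (median -3.12) and all 15 measured AT2 genes were higher (median 5.24). Marker genes could take part in the clustering, so these values are not independent of how the classes were formed and named. The sort gate list had 1 of 3 measured genes lower (median -0.39). Basal, neuroendocrine, tuft, endothelial, immune, mesenchymal and erythroid genes did not reach the count minimum, at 4.25, 8.50, 8.50, 17.0, 8.50, 8.50 and 8.50 summed CPM in AT2-like cells. Over the 18 gene group lists, 42 of 156 measured members were higher, 40 lower and 74 neither. Without the last 96 columns, 31 were higher and 35 lower, with Anxa1 at -4.12, Gsto1 at -4.38, Reg3g at -3.36 and Lcn2 at 2.06. Cldn10 was then at -2.89, a bound, since no AT2-like count of it was left. Psap (-0.76), Ifitm3 (-1.06), Ly6a (-1.72) and H2-D1 (0.92) were no longer called.

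Over all 4079 measured genes the median log2 ratio was 0.19, and it was -0.12 with TMM factors and -0.02 with totals that leave out Scgb1a1 and Sftpc, which gave 32 higher and 48 lower, and 36 higher and 46 lower list members, with Nkx2-1 (0.94), Fos (0.84) and Npc2 (0.78) under 2-fold with TMM factors. Without the cell of most counts in each class, Fabp5 was at 8.26, H2-Aa at 6.38, Ly6a at -4.08 and Reg3g at -1.66, the last no longer called. Cldn10 was at -4.17, a bound, since no AT2-like count of it was left.

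**Figure D4:**
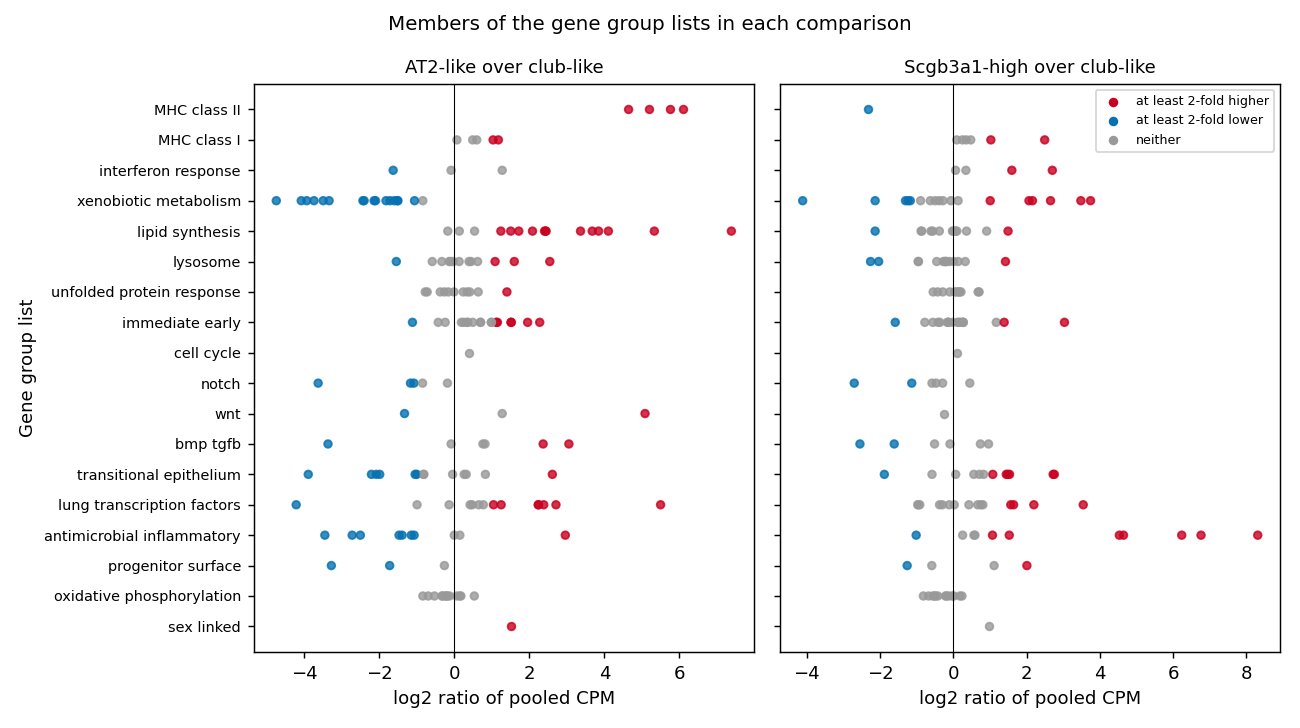
The log2 ratio of pooled CPM to club-like cells (horizontal) for each measured member (point) of the 18 gene group lists (vertical), with AT2-like cells on the left and Scgb3a1-high cells on the right, coloured by whether the member was called at least 2-fold higher, lower or neither. In AT2-like cells 13 of 16 lipid synthesis genes are higher and 16 of 17 xenobiotic metabolism genes lower, and in Scgb3a1-high cells 7 of 11 antimicrobial genes are higher.

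Scgb3a1-high cells were set against club-like cells as the remaining class. Most measured genes of the antimicrobial and inflammatory list were higher in them, and so were several transitional epithelium genes. Bpifa1 and Bpifb1, secreted proteins of the airway surface, were 318-fold (95% interval 245 to 421) and 109-fold (78.0 to 156) higher. The antimicrobial lectin Reg3g was 75.4-fold higher (57.8 to 100) and the neutrophil chemokine Cxcl5 25.1-fold (9.41 to 94.2), while Npc2 was lower at a ratio of 0.244 (0.207 to 0.285). Bpifa1 and Bpifb1 lie on chromosome 2 (154142880 to 154149219 and 154190818 to 154220369).

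Of 11 measured antimicrobial and inflammatory genes 7 were higher and 1 lower (median log2 ratio 1.53, percentile 100), with medians of 0.94, 1.71 and 4.52 within the 3 sets of columns, the last from 3 Scgb3a1-high cells. Pigr was 2.88-fold higher (2.39 to 3.50), and Lcn2 was lower at a ratio of 0.495 (0.265 to 0.887), which came from the middle set alone (log2 ratios of 0.72, -3.40 and 3.69 within the sets, from 20, 37 and 3 counts). Of 12 transitional epithelium genes 6 were higher and 1 lower (median 0.95, percentile 99.98, and 1.06, 1.26 and 0.41 within the sets). S100a6 was 6.62-fold higher (5.46 to 8.07), Anxa1 2.80-fold (2.26 to 3.49) and Krt19 2.73-fold (2.35 to 3.16). Of 18 xenobiotic metabolism genes 6 were higher and 5 lower (median -0.34, percentile 0.89, and -0.30, -0.15 and -0.11 within the sets). Gsto1 was 4.19-fold higher (3.74 to 4.70), Cyp4b1 was neither, and Gstm2 was lower at a ratio of 0.405 (0.306 to 0.530). Of 15 lung transcription factors 4 were higher and 0 lower (median 0.43, percentile 99.3, and 0.52, 0.68 and 0.52 within the sets). Of 4 interferon response genes 2 were higher (median 0.97, percentile 99.2), and of 6 class I genes 2 were higher (median 0.41, percentile 96.6), with H2-K1 and H2-D1 neither.

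The single measured MHC class II gene, Cd74, was lower at a ratio of 0.200 (0.051 to 0.581) from 4 counts. The 14 lysosome genes had a median of -0.22 (percentile 15.0), with Ctsc lower at a ratio of 0.209 (0.106 to 0.378). Of 14 lipid synthesis genes 1 was higher and 1 lower, Scd1 at a ratio of 0.228 (0.125 to 0.391), with a median of -0.01 (percentile 51.1) and 0.05 with TMM factors. Of 18 immediate early genes 2 were higher and 1 lower (median 0.05, percentile 89.7, and -0.11 with totals without Scgb1a1 and Sftpc), Klf4 being 8.20-fold higher (5.73 to 12.1). Of 6 Notch genes 2 were lower (median -0.53, percentile 4.76), with Hes1 at a ratio of 0.456 (0.346 to 0.595), and of 6 BMP and TGF-beta genes 2 were lower (median -0.30, percentile 22.3), with Id2 at 0.327 (0.109 to 0.826). Of 4 progenitor surface genes 1 was higher, Ly6a at 4.03-fold (2.88 to 5.71), and 1 lower (median 0.26, percentile 85.3). Unfolded protein response genes (11 measured, median 0.08, and -0.08 with totals without Scgb1a1 and Sftpc) and oxidative phosphorylation genes (13 measured, median -0.21) had none higher or lower, nor had the 1 measured gene each of the cell cycle, Wnt and sex-linked lists (Pcna, Ccnd1 and Ddx3y). Outside the lists, the sulfhydryl oxidase Qsox1 was 3.28-fold higher (2.71 to 3.99).

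The members named next lie outside the rule and were chosen after their values were seen. The 4 higher transcription factors in Scgb3a1-high cells were Sox9, a factor of distal progenitors and glands, at least 11.7-fold from 28 counts against 0, the epithelial factor Elf3 at 2.97-fold (2.16 to 4.12), Foxp2 at 4.59-fold (1.81 to 13.8) and Tfcp2l1 at 3.13-fold (1.45 to 7.31). The higher interferon response genes were Ifit1 at 6.51-fold (2.46 to 21.7) and Ifi27 at 3.03-fold, and the higher class I genes H2-T23 at 5.64-fold and Psmb8 at 2.04-fold. The 5 lower xenobiotic genes were Cyp2b10, Cyp2s1, Gstm2, Ephx1 and Nqo1, with Cyp2s1 at 0 counts against 65, of which 49 lay in the 10 ciliated-like cells. Fdps was the lipid synthesis gene that was higher (2.82-fold), and Hspa1b was the other immediate early gene that was higher (2.62-fold). Lower members were the cell cycle inhibitor Cdkn1a of the transitional list at a ratio of 0.271 (0.161 to 0.438), the cytokine signalling inhibitor Socs3 at 0.333 (0.213 to 0.506), Notch1 at 0.153 (0.054 to 0.358), Itgb4 at 0.418, and Bmp4 with 0 counts against 22.

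Cell type markers could take part in the clustering, and Tff2, Muc5b and Agr2 were leading genes of this class, so their values repeat how it was described. Among cell type lists, 3 of 4 measured goblet genes were higher (Muc5b, Agr2 and Tff2; median 4.09), as were both measured basal genes, Krt15 and Aqp3, and all 4 measured ciliated genes were lower (median -2.85), with nearly all club-like counts of Foxj1, Tppp3 and Ccdc153 in the 10 ciliated-like cells. Of 12 club genes 4 were higher and 1, Hp, was lower (median -0.09), of 9 AT2 genes 1 was higher and 6 lower (median -1.47) and of 6 AT1 genes Pdpn was higher and Ager and Hopx lower (median -0.63). Neuroendocrine, tuft, endothelial, immune, mesenchymal and erythroid genes summed to 8.80, 2.20, 2.20, 2.20, 4.40 and 0 CPM in Scgb3a1-high cells, and none of the 3 measured sort gate genes was higher or lower. Without the 10 ciliated-like cells, S100a6 was at a log2 ratio of 3.77, above its 2.73 with them.

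Over the 18 lists 32 of 156 measured members were higher, 17 lower and 107 neither, and with totals that leave out Scgb1a1 and Sftpc 27 were higher and 24 lower, while the median of all 4550 measured genes was -0.05. Without the cell of most counts in each class, Bpifa1, Bpifb1 and Reg3g were at log2 ratios of 9.28, 7.57 and 7.41 (from 8.31, 6.76 and 6.24), and the calls of Hes1, Id2 and Lcn2 were lost in some alternatives, Id2 being at -0.91 with 1000 variable genes, Hes1 at -0.82 with 10 principal components, and Lcn2 at -0.65 with the mean CPM per cell.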

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

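All tests in this part were chosen after the result was seen, except the thinning test of AT2-like shares and the test of totals of the 10 ciliated-like cells, which were written before. No biological explanation was tested for any pattern, since the labels give a single group of sorted cells.

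Wells removed for low totals still held signal. Of the 59 removed wells, 48 held more counts than the higher control well. Among them, 16 held over 100 Sftpc counts (0 in both controls), 4 held 15 or more counts of the ciliated list (at most 1 in a control), and 2 held 40 or more counts of S100a8 and S100a9, calcium-binding proteins abundant in myeloid cells, which had 0 counts in the controls and in each kept cell.

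AT2-like cells made up 64.1% of kept cells in the last 96 columns, against 6.10% and 21.0% in the first and middle sets. Lower depth there did not account for it among the cells deep enough to thin, which were 44 of the 64 kept cells of that set. After thinning each cell to 3151 counts and clustering again, the share in the last set was 54.5% (38.8 to 69.6%, 44 cells). This was above the upper bound of 27.9% in the middle set (79 cells). The shallower cells were not covered. Sftpc spread between those wells did not account for it either, since the xenobiotic metabolism genes, which had no part in the clustering, were at a median log2 ratio of -2.29 (-2.73 to -1.80) to club-like cells within that set, where dilution by Sftpc at 16.0% of counts gives -0.25. Removal of wells of low totals did not account for it: with the removed wells of over 100 Sftpc counts added (6, 1 and 9 in the 3 sets) and all sorted wells as denominator, the share was 11.7%, 18.8% and 52.1% (41.6 to 62.4%), the last above the upper bound of 28.0% in the middle set. Whether those columns came from another plate, animal or sort is not given in the labels, and this stays open.

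Scgb1a1 counts in AT2-like cells were compared with carry-over between wells (or free RNA) and with a second, club-like cell in the well. The other classes were pooled over all sets of columns. The last set, with 41 of the 63 AT2-like cells, kept only 3 Scgb3a1-high cells, so proportions there may differ. If carried-over counts keep the proportions of the other classes, which was not tested, the other club markers would stay at the ratio of Scgb1a1. Over all 63 cells, 6 of 11 lay wholly below it (Scgb1a1 at 15.3% of its level in the other classes, Scgb3a2 at 2.98%), which just reached the bound set for counting against carry-over. That result rests on 10 cells of at least 200 Scgb1a1 counts, which held 81.7% of the class's Scgb1a1 counts; in the other 53 cells 3 of 11 markers lay below, short of that bound, and counts carried over from other wells or free RNA and the cells' own transcripts cannot be told apart. The 39 cells above the controls had a median total of 3626 counts, against 5487 in club-like cells. That argues against a second cell of the usual club-like depth in most of these wells, although in the first set the 5 such cells had 5042 against 5300. Of the 10 cells of at least 200 Scgb1a1 counts, 5 held fewer of them (225 to 426) than any of the 88 club-like cells outside the ciliated-like cluster (lowest 580). Of these 5, 4 held at most 2 Scgb3a2 counts, as did 5 of the 88. In those 5 wells these counts argue against a second, club-like cell as deep as kept ones, though the wells were picked by their low Scgb1a1 counts. A second cell of low yield stays possible, as removed wells held 424 and 2, 488 and 0, and 261 and 1 counts of Scgb1a1 and Scgb3a2. In the other 5 a second, club-like cell stays a candidate explanation. There the summed count of the 11 other club markers lay within the middle 95% of those club-like cells (179.9 to 1054.7) in 4. All 5 were below the club-like median of 495.5, at 156 to 292 (median 218). They held 10 to 54 Scgb3a2 counts, against a club-like median of 101. AT2-like cells under 200 Scgb1a1 counts held some of these markers too (ratio to the other classes 0.338 for Cbr2, 0.009 for Scgb3a2). The sum therefore cannot decide for a second cell. The 10 cells also had a median total without Scgb1a1 of 4444 counts, against 3298 in the other AT2-like cells. They lay 3, 2 and 5 in the 3 sets of columns, which differ in depth, while all AT2-like cells lay 5, 17 and 41. This contrast therefore cannot tell a second cell from the depth of the sets.

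Ciliated markers were concentrated in a cluster of 10 cells of the club-like class, of which 8 held 242 of the 247 counts of the ciliated list and the other 2 held 1 and 4. Counts carried over evenly from other wells would be spread over the class, but when cells were clustered again without the genes of that list, the cluster with these 10 cells, of 16 club-like cells in all, held 93.6% of the class's ciliated list counts (89.9 to 96.2%). A second cell in the well could not be decided over all 10 cells: their median total of 5430 was just under the 5487 of the other club-like cells, which met the bound written against it, but by far less than the spread of those cells (quartiles 4835.5 to 7015.8), and the 8 cells alone had a median of 6008.5. In the 4 cells of at least 1000 Scgb1a1 counts a second cell in the well stays a candidate explanation, as 4 of 4 had a total above the upper quartile of their set. The other 4 of the 8 cells held 6 to 24 Scgb1a1 counts, where the lowest of the 88 other club-like cells held 580. They held at most 2 Scgb3a2 counts, where the median was 101. This argues against a second, club-like cell as deep as kept ones, but 1 of low yield cannot be excluded. The sum of the 11 other club markers lay within the middle 95% of the 88 cells in 2 of the 4.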

How the results depend on the processing

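Of the 26 alternatives run, 19 were planned and 7 (totals without ribosomal RNA, totals without Scgb1a1 and Sftpc, counts above the control wells, no control limit, and comparisons without ciliated-like cells, the last 96 columns or the top cell) were chosen after seeing the data. Spike-in scaling was not run, as the table used here holds no spike-in genes; the pseudocount and low-value alternatives apply to normalized values only; and dropping the mitochondrial filter removed nothing and tests nothing. No paired analysis was possible because no label names an animal and the cells and control wells share only numbers. Of 672 list medians under alternatives, 631 stayed within the interval of the reported value, 40 lay outside and 1 reversed, and of 2769 named gene ratios these numbers were 2678, 88 and 3. Of 1522 values of the 67 called gene ratios, 1432 kept the call. These tallies include settings that could not move a gene ratio. Requiring 200 genes and leaving out the first control kept the same 227 cells. The 1.5-fold and 3-fold rules alter only calls, and the count minimum alters only which genes enter. The numbers that stayed therefore overstate how stable the results are. The reversals were of Bpifa1 in AT2-like cells, from -1.07 to 0.024 with at least 1000 genes, 0.0097 with 1000 variable genes and 0.051 with scran size factors, and of the progenitor surface median, from -1.73 to 0.052 without the count minimum, which adds genes of few counts. In Scgb3a1-high cells the log2 ratios of Reg3g (6.24), Bpifb1 (6.76) and Bpifa1 (8.31) kept their call but were 7.51 to 8.06, 7.52 to 8.50 and 9.08 to 9.29 with other clusterings or at least 1000 genes, and 6.92 for Reg3g and 7.38 for Bpifb1 with the mean CPM per cell. The cause was not tested for the other changes except where the alternative itself sets the value.

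Leaving out each control in turn gave a median total of 20.5 to 117 times the higher control, 227 to 250 cells kept, 218070 to 223932 CPM of Scgb1a1 and 29251 to 31366 CPM of Sftpc, 117, 250, 218070 and 31366 being the values without the second control. With no control limit these were 218070 and 31366 CPM. Sftpc was 28548 CPM with at least 1000 genes. Thinned cells had 217469 CPM of Scgb1a1 and 34057 of Sftpc, Epcam in 23.5% of cells, and Sftpc, and so both genes, in 48.0%. From 3 counts, Epcam was positive in 1.76%, Sftpc in 32.6% and both genes in 31.3% of cells, and above the controls both were found in 51.1%. Scgb1a1 and Sftpc had 248977 and 32523 CPM on totals without ribosomal RNA, and 299849 and 39168 on totals without themselves, which the smaller denominators set. The club-like share was 36.6% with 10 principal components, and without the last 96 columns the Scgb3a1-high share was 38.7% and the AT2-like share 13.5%. With at least 100 counts per gene, fewer genes entered, and 21 list members were higher and 22 lower in AT2-like cells, and 21 higher and 7 lower in Scgb3a1-high cells. At 1.5-fold, 27 were lower in Scgb3a1-high cells; at 3-fold, 26 were lower in AT2-like cells, and 20 higher and 11 lower in Scgb3a1-high cells. Low depth limits rare genes: a count of 0 in 227 cells allows up to 1.32% of cells with a count.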

Other observations

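The values in this part were chosen after the data were seen. At resolution 1.0 the Scgb3a1-high class was split in 2 main clusters. In a cluster of 25 cells Bpifa1 had 66153 CPM (64959 to 67364), the iron-binding Ltf 4095 CPM and the basal keratin Krt15 595 CPM, the last from 9 cells. A cluster of 43 cells, 41 of them Scgb3a1-high, had 8503 CPM of Bpifa1 and 2773 CPM of the mucin Muc5b, against 1920 CPM of Muc5b in the other. Keratin Krt8 and the galectin Lgals3 had 2696 and 1337 CPM in the 25 cells and 1417 and 612 CPM in the 43. Retnla, a secreted resistin-like protein, had its highest level in a cluster of 15 club-like cells, at 3783 CPM. The 10 ciliated-like cells had 880 CPM of Foxj1, the ciliogenesis factor (chromosome 11, 116330704 to 116335399), 1817 CPM of Tppp3 and 1186 CPM of Cd24a, above the 490 CPM of Cd24a over all kept cells. Several of these genes took part in forming the clusters, so the levels describe the clusters and are not differences found independently of them.

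Even counts were more common than odd ones for some abundant genes. Scgb1a1 counts were even in 72.2% of kept cells (65.9 to 78.0%), Rn45s in 72.7% (66.4 to 78.4%) and Actb in 62.6% (55.9 to 68.9%), while Malat1 was even in 48.2% (41.5 to 55.0%). Of 32 genes with a mean of at least 10 counts, the median share of even counts was 52.4%, and 8 genes were above 60%.

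Stxbp3-ps and Scn2b, at 65 and 41 of the 234 counts of the second control, had 0 counts in the first control and up to 54 and 50 in a sorted cell. Of the removed wells, 11 had over 50% of their counts from Rn45s, and no kept cell did.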
